A study of Danio rerio with 12 samples.

How the data were processed

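Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in cells sorted from whole zebrafish embryos at 72 hours post fertilisation. The embryos carried a kdrl:mCherry and a sele:GFP transgene, and per the labels' protocols 12000 to 50000 cells of each of 4 fractions were used. The fractions were cells positive for both reporters (double positive), for mCherry but not GFP (mCherry only), for GFP but not mCherry (GFP only) and for neither (double negative). Each group held 3 samples, 12 in all, and the group of each sample was taken from its title.

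One peak list per group was analysed, and the labels name that same list for all 3 samples of the group. A group is therefore 1 pooled list, with no replicate check, and no p-value was computed across peaks, which are not replicates. Per the submitters' processing notes, Bowtie2 2.2.1, MACS2 2.1.0 and the danRer7 genome build were used. The settings of the caller, the filters on reads, the treatment of Tn5 offsets and the way the samples were pooled are not given in the sources used here. Peak coordinates were used in danRer7 as the authors deposited them and are printed 1-based.

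In the lists the authors deposited, each peak has a display score, a fold enrichment, a −log10 p, a −log10 q and a summit position. The fold (a linear ratio over the expected background at the summit), the −log10 values and the score are the authors' own per-peak values. They served to describe, rank or filter peaks, and the fold and −log10 p also gave the read numbers described next. The other deposited column, the summit offset in bp, gave the position of each summit. The display score was not used further, since in nearly every peak it equalled 10 times −log10 q, rounded down.

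The number of reads at each summit was recovered from the fold and the −log10 p together. It was taken as the whole number of reads, with its expected background, that gives both values under a Poisson tail and a pseudocount of 1 in the fold. The largest misfit of −log10 p was 0.000382 over all lists, whereas the second-best whole number missed by at least 0.00808. On peaks simulated with the same formulas, 20000 drawn for each list, 100% of the read numbers were recovered. That checks the recovery and not whether the formulas hold for the deposited lists. The lowest expected background in a list was taken as its genome-wide background: 3.63 reads for double positive, 4.46 for mCherry only, 4.26 for GFP only and 4.47 for double negative. Height is the number of reads at the summit divided by that background, so that lists of different depth share a scale. The pileup model is inferred from the values and was not stated in the sources used here.

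Peaks were called shared when they overlapped by 1 bp or more. Each peak was classed by the set of lists that shared it. This classification was right for 100% of peaks in simulated lists built from 20000 regions of known pattern. Those regions lay well apart and the peaks of a region always overlapped. The simulation therefore checks the computation only, and not how split, merged or close peaks are classed. Random placement moved each peak within its chromosome 100 times. Wilson 95% intervals for shares and exact Poisson 95% intervals for reads cover counting error only. For runs of peaks, summits of a class were chained over gaps of at most 20 kb, and chains of 5 or more peaks were counted. Closeness was the share of a class with a summit of another class within 10 kb. Both were set beside draws of other peaks of the same list, matched on chromosome and on 10 bins of height with equal numbers of peaks. Where a bin held too few other peaks, they were drawn with replacement. There were 1000 draws for runs in classes of up to 20000 peaks, and 100 for larger classes and for closeness. Peaks of the neighbouring class were kept out of the draws for closeness. The contrast between GFP-positive and GFP-negative lists is the mean log2 share of peaks in the former minus that in the latter, computed also in 278 windows of 5 Mb with at least 400 peaks over the 4 lists.

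The groups, the classes, the overlap rule, the random placement and 6 of the 9 alternatives were chosen before the data were examined. Recovered reads, heights, runs, closeness, chromosome 4, the windows and the 3 alternatives that filter on height were chosen after seeing the data. Regions were named by a rule fixed in advance for the case without an annotation: the 10 peaks of each class with the highest fold on placed chromosomes. Members of runs are the exception, and were chosen after their values were seen.

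No genome sequence or gene annotation of danRer7 was used here, and the gene table at hand belongs to another assembly, GRCz12tu. Planned results on transcription start sites, gene lists and sequence motifs were therefore not run, and the loci of kdrl, sele and mrc1a were not analysed here. Whether a region lies in a gene, an exon or an intron is for the same reason not given. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.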

Results

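Open chromatin was compared between 4 fractions of cells sorted from zebrafish embryos at 72 hours post fertilisation. The transgene kdrl:mCherry marks vascular endothelium, since kdrl encodes a receptor for vascular endothelial growth factor. The transgene sele:GFP reports on sele, which encodes E-selectin, an adhesion molecule of endothelial cells. With both reporters, cells were separated into double positive, mCherry only, GFP only and double negative fractions of 3 samples each. The series concerns the vascular niche of blood stem cells, and the comparison asks which accessible regions set the double positive fraction apart. Each fraction is represented by 1 list of peaks in the danRer7 build, so no difference described here has a replicate check.

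The double negative list was the longest, with 166285 peaks, and the double positive list the shortest, with 90689. The mCherry only list held 134262 peaks and the GFP only list 138366. They covered 73.2, 38.0, 57.6 and 55.1 Mb in the same order. Median peak width was 379 bp for double negative, 353 bp for double positive, 366 bp for mCherry only and 341 bp for GFP only. The median number of reads at the summits of called peaks was 26 for double positive, 28 for mCherry only, 25 for GFP only and 26 for double negative. The genome-wide background of the double positive list was 0.813 of that of the double negative list, that of mCherry only 0.999 and that of GFP only 0.955.

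The lists differed in length mostly through low peaks. The double negative list was 1.83 times as long as the double positive list over all peaks, 1.20 times as long among peaks of height 10 or more, and 0.862 times as long at height 20 or more. At that height the double positive list held 10438 peaks, mCherry only 9977, double negative 9001 and GFP only 7729. Height is the number of reads at the summit over the background of the same list. Median height was 7.16 for double positive, 6.28 for mCherry only, 5.86 for GFP only and 5.82 for double negative.

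In the lists as called, most regions open in double positive cells were called in every fraction. Of the 90689 double positive peaks, 56304 (62.1%, Wilson 95% interval 61.8 to 62.4) overlapped peaks of all other lists. That share was not computed under the alternatives. It must be lower with lists of equal length, where 56.8% of double positive peaks lay in the double negative list. Among the peaks not in all lists, mCherry only was the most frequent partner. The mCherry only list held 84.9% of the double positive peaks (84.7 to 85.1), the double negative list 74.3% (74.0 to 74.5) and the GFP only list 72.5% (72.2 to 72.8). Placed at random on the same chromosomes, the double positive peaks met these lists in 8.22%, 10.3% and 8.18% of cases on average. In bases, the overlap (Jaccard index) with double positive was 0.489 for mCherry only, 0.377 for GFP only and 0.320 for double negative.

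In the reverse direction, 56.6% of mCherry only peaks, 47.4% of GFP only peaks and 39.9% of double negative peaks overlapped a double positive peak. The mCherry only peaks lay in the GFP only list in 65.7% and in the double negative list in 72.1% of cases. The GFP only peaks lay in the mCherry only list in 64.5% and in the double negative list in 68.4% of cases. The most frequent partner of these lists depended on the setting. With lists of equal length 72.4% of mCherry only peaks lay in the double positive list and 63.4% in the double negative list, and double positive was also the higher one among peaks of height 7 or more and 10 or more. With equal length 66.5% of GFP only peaks lay in the mCherry only list and 60.8% in the double negative list. For double negative peaks the shares as called were 57.9% in mCherry only and 56.1% in GFP only. In bases, the Jaccard index was 0.443 for mCherry only with GFP only, 0.432 for mCherry only with double negative and 0.395 for GFP only with double negative. The order of the GFP only and double negative lists as partners of double positive depended on the setting. The GFP only share was the higher one in 3 of the 9 alternatives, while the mCherry only share was the highest in all 9.

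**Figure D1:**
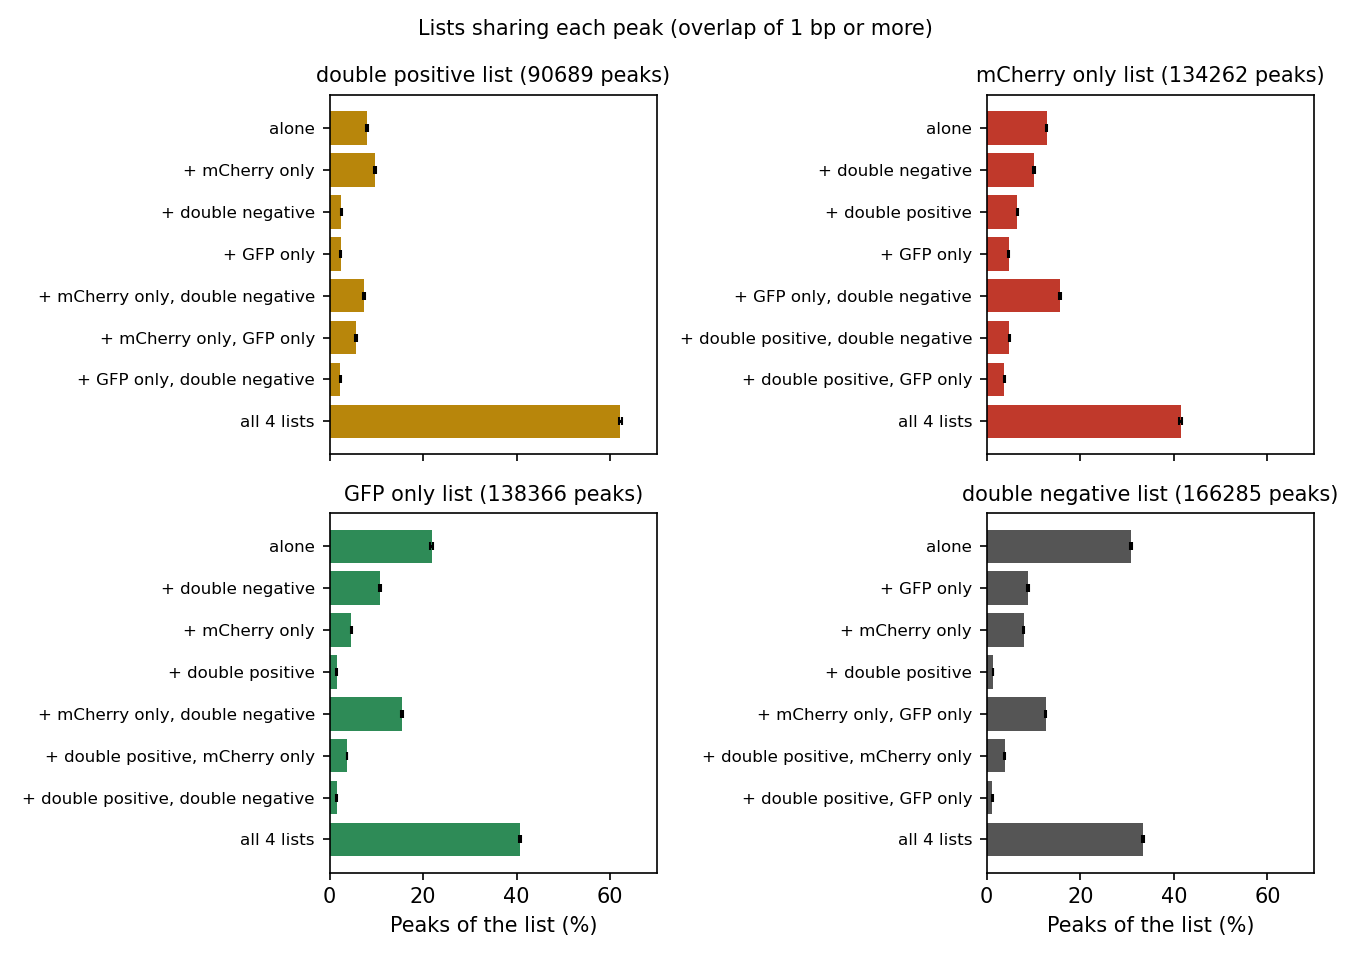
Percent of the peaks of each list (x axis) by the lists that share them (y axis), with 1 panel per list and Wilson 95% intervals as error bars. Peaks shared by all 4 lists made up 62.1% of the double positive list and 33.5% of the double negative list, whereas peaks of 1 list alone made up 7.93% and 30.8%.

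The mCherry only share was the highest in every bin of height from 4 upwards. Below height 4, 53.3% of double positive peaks lay in the mCherry only list, 55.0% in the double negative list and 50.5% in the GFP only list. From height 6 to 8 the shares were 89.7%, 74.9% and 72.5%. At height 20 or more, 10411 of 10438 double positive peaks (99.7%, 99.6 to 99.8) were also called in mCherry only, against 93.8% in GFP only (93.3 to 94.3) and 92.3% in double negative (91.8 to 92.8).

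**Figure D2:**
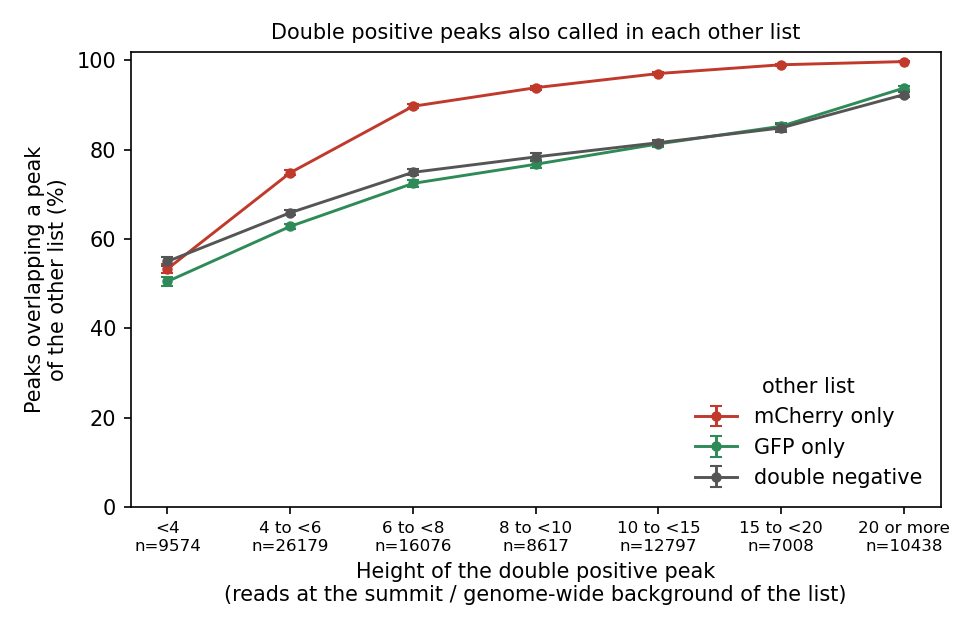
Percent of double positive peaks that overlap a peak of each other list (y axis), by the height of the double positive peak (x axis, reads at the summit over background, n peaks per bin). Points are shares with Wilson 95% intervals; the mCherry only share rose from 53.3% to 99.7%, and the GFP only and double negative shares ended at 93.8% and 92.3%.

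Regions open in both mCherry-positive fractions and called in neither other fraction formed the largest class of double positive peaks in the lists as called, after those in all 4 lists. This class held 8847 peaks (9.76% of the list, 9.56 to 9.95). With lists of equal length the peaks of double positive alone were more numerous (16481 against 11580), as they were with reciprocal overlap of 50% (14096 against 11332). The class was 4.11 times as large as the class shared with GFP only, which held 2154 peaks (2.38%, 2.28 to 2.48). Under the 9 alternatives the class was 2.90 to 58.5 times as large. Its median height was 6.88, against 4.41 in the GFP only class and 8.81 in peaks of all 4 lists. Of its peaks, 444 reached height 20, against 4 in the GFP only class; in the partner lists, 89 of 8779 mCherry only peaks and 6 of 2113 GFP only peaks did. A further 5156 double positive peaks (5.69%) were shared by all 3 reporter-positive fractions and absent from the double negative list. That count was 7816 with lists of equal length and 1332 with height 10 or more in the counted list.

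The 10 regions of the mCherry-positive class with the highest fold lay on 7 chromosomes and had folds of 14.5 to 16.6. The leading region lay on chromosome 6 from 31006095 to 31006602. It had a fold of 16.6 and 89 reads in the double positive list (exact Poisson 95% interval 71.5 to 110), and 48 reads in the mCherry only list. On chromosome 23, the region from 14304955 to 14305428 had 117 reads (96.8 to 140) and 93 reads in the mCherry only list. That from 14807961 to 14808438 on the same chromosome had 128 reads (107 to 152), the most of the 10, and 70 reads in mCherry only. The others had 72 to 105 double positive reads and folds of 14.5 to 15.6.

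Heights in these regions tended to be larger in the double positive list, though the direction depended on which list selected the regions. Height above background was compared, with the reads of each list scaled by its own background. In 2010 regions of the class the heights in both lists had a geometric mean of 10 or more. There the mCherry only value was 0.714 of the double positive value in the median (quartiles 0.496 and 1.13). The median was 1.06 in 27338 regions of all 4 lists (0.912 and 1.25). Selected on double positive height alone, the class gave 0.556 over 2516 peaks, and selected on mCherry only height it gave 1.23 over 1882 peaks.

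Peaks of the mCherry-positive class were clustered along the genome. They formed 52 runs of 5 or more peaks with gaps of at most 20 kb, against a mean of 6.62 and a maximum of 15 in 1000 matched draws of other double positive peaks. The longest run held 9 peaks of the class, as did the longest in any draw (mean 6.06), and lay on chromosome 18 from 30513887 to 30575955. The double positive list had 12 peaks there, mCherry only 15, GFP only 5 and double negative 6. Another run held 8 peaks on chromosome 11 from 18863625 to 18892538, with up to 123 reads. The number of runs ranged from 3 with a height of 10 or more in the counted list to 119 with lists of equal length. It was 7.86 times the mean of the draws, and exceeded the mean of the matched draws under all 9 alternatives.

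**Figure D3:**
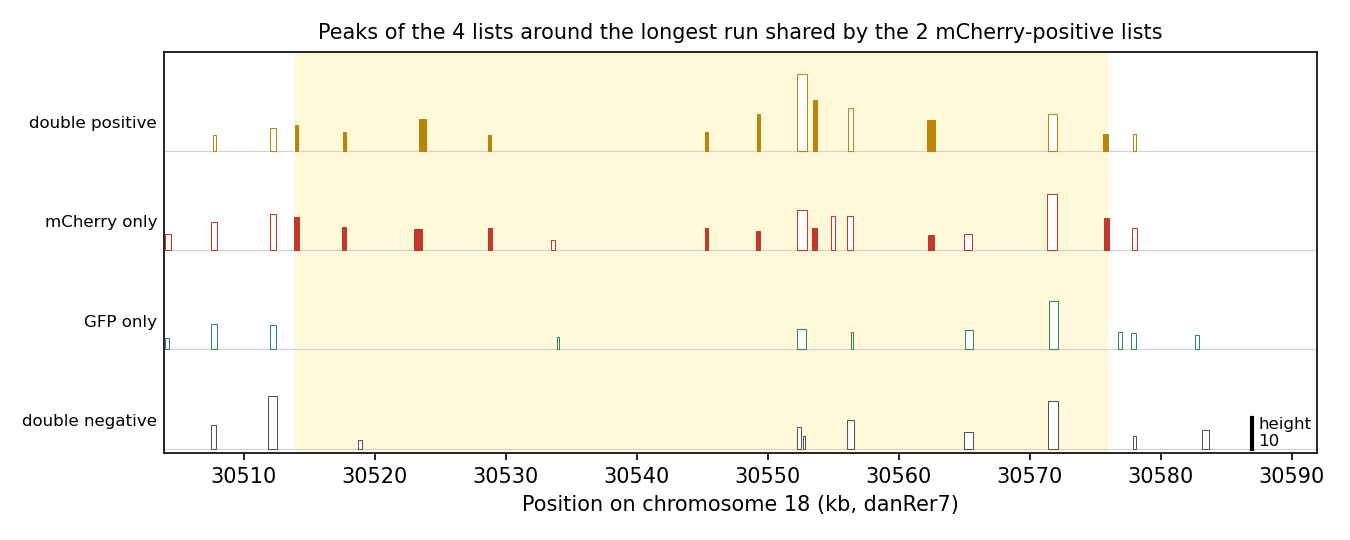
Peaks of the 4 lists around the longest run of the class shared by both mCherry-positive lists, on chromosome 18 of danRer7 (x axis, kb; shaded from 30513887 to 30575955). Bars span each peak, their height is reads at the summit over background (scale bar, 10), and filled bars are the 9 regions of the class in each of the 2 lists.

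Regions open in both GFP-positive fractions and called in neither other fraction were few and low. Of the 2154 double positive peaks in this class, 43 reached height 10 and 4 reached height 20, and the highest fold was 7.79. A similar number of double positive peaks, 2257, had double negative as their only partner, and 48 of those reached height 10. Of the 2113 GFP only peaks, 98 reached height 10 and 6 reached height 20, and the highest fold was 12.5. The leading region lay on chromosome 7 from 34970127 to 34970511, with 47 reads in the double positive list (34.5 to 62.5) and 19 in the GFP only list. A region on chromosome 16 from 25554363 to 25554741 had 50 reads (37.1 to 65.9), with 46 reads in the GFP only list. The class shrank to 599 peaks with −log10 q of 5 or more in the counted list and to 884 with that threshold in every list. It grew to 3905 peaks with reciprocal overlap of 50%.

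In the lists as called, few regions were open in double positive cells alone, and these were low, as in the other classes of 1 list alone. The 7190 peaks called in this list only (7.93%, 7.75 to 8.11) had a median height of 4.41, and 9 reached height 20. Median height was 4.26 for mCherry only alone, 4.46 for GFP only alone and 4.48 for double negative alone. The highest fold was 9.93, on chromosome 2 from 56671819 to 56672164, with 45 reads (32.8 to 60.2). A region on chromosome 17 from 24736701 to 24737390 followed, with 49 reads (36.3 to 64.8), and the 10 leading regions lay on 9 chromosomes with 38 to 52 reads. The count moved from 2549 with −log10 q of 5 or more in the counted list to 16481 with lists of equal length. The latter exceeded the 9884 of mCherry only alone, but equal length keeps the double positive list whole and shortens the others. Of the 7190 peaks, 325 had a height of 10 or more. The class formed 3 runs, against a mean of 1.33 and a maximum of 8 in draws.

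Of the single-reporter fractions, GFP only had the tallest regions of its own. Its 30143 exclusive peaks (21.8% of the list, 21.6 to 22.0) included 2765 of height 10 or more, and 158 of height 20 or more. The mCherry only list had 17185 exclusive peaks (12.8%, 12.6 to 13.0), of which 408 reached height 10 and 8 reached height 20. The leading GFP only region lay on chromosome 14 from 8855537 to 8856295, with a fold of 17.0 and 104 reads (85.0 to 126). The leading mCherry only region lay on chromosome 8 from 3826315 to 3826847, with a fold of 10.4 and 56 reads (42.3 to 72.7). On chromosome 1 from 58373911 to 58502621, 14 exclusive mCherry only peaks formed the longest run of that class, within the range of its draws (maximum 15). Both ends of that run were among its 10 leading regions, with folds of 9.71 and 9.89. The longest GFP only run held 26 peaks (maximum in draws 21) on chromosome 1 from 52806516 to 52925190. There were 125 runs in the mCherry only class (draws: mean 66.2, maximum 96) and 646 in the GFP only class (mean 490, maximum 534). With a height of 10 or more asked of the counted list, these classes held 408 and 2765 peaks.

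The double negative fraction, whose gate took cells of the embryo without either reporter, had the most exclusive peaks when peaks of every height were counted. There were 51181 of them (30.8%, 30.6 to 31.0), of which 1848 had a height of 10 or more and 20 a height of 20 or more, fewer than the 2765 and 158 of GFP only alone. The leading region lay on chromosome 1 from 54192078 to 54192458, with 92 reads (74.2 to 113). Exclusive double negative peaks formed 2847 runs (draws: mean 2570, maximum 2630), and the longest held 60 peaks (maximum in draws 38) on chromosome 16 from 76095 to 520841. The count fell to 24560 with lists of equal length and to 28744 with −log10 q of 5 or more in the counted list.

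The GFP-positive lists had a larger share of their peaks on chromosome 4 beyond 25 Mb than the GFP-negative lists. There lay 2126 of the 90689 double positive peaks (2.34%) and 3459 of the 138366 GFP only peaks. In the GFP-negative lists these were 2514 of 134262 mCherry only peaks (1.87%) and 3139 of 166285 double negative peaks (1.89%). In number of peaks, GFP only had the most there and double positive the fewest. The larger share of double positive therefore rests on the shortness of its list. The contrast of GFP-positive against GFP-negative lists was 0.36 on the log2 scale (95% interval 0.31 to 0.42, counting error only), and the corresponding contrast by mCherry was −0.05. Of 278 windows of 5 Mb, the 7 with the highest GFP contrast all lay on chromosome 4, between 30 and 65 Mb, at 0.30 to 0.47. The highest elsewhere was 0.29, on chromosome 22. The contrast was 0.79 with lists of equal length and 0.26 (0.11 to 0.41) among peaks of height 10 or more. Equal length keeps the double positive list whole and removes the weakest peaks of the others, which can raise the contrast by itself.

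**Figure D4:**
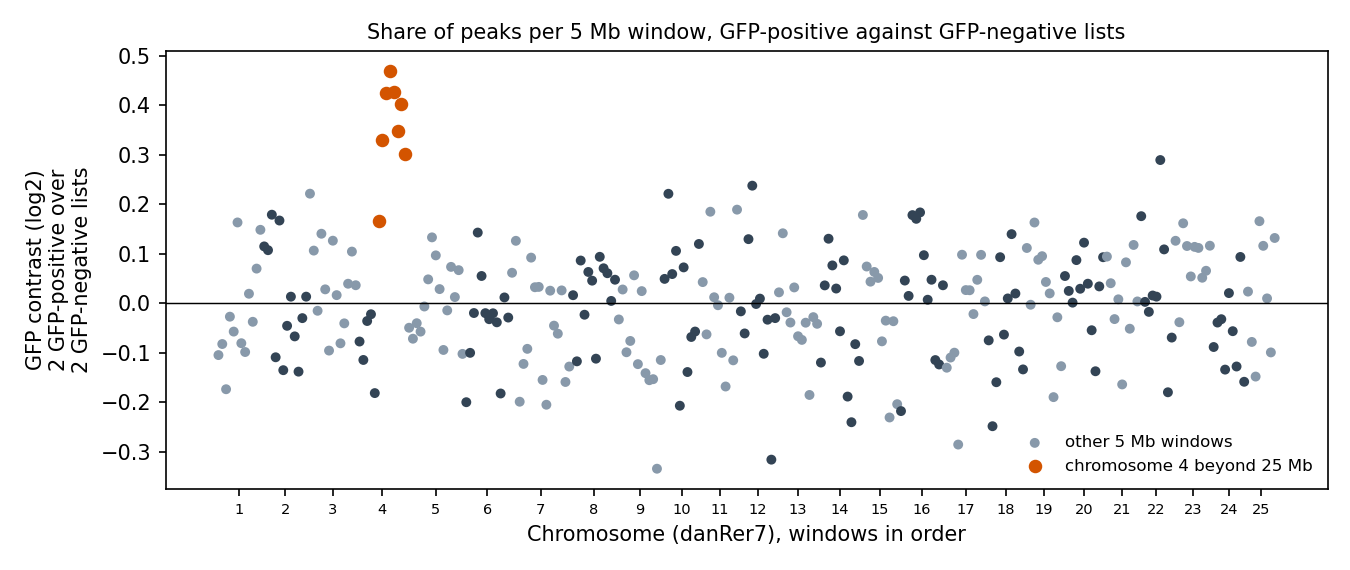
Contrast of GFP-positive against GFP-negative lists (y axis, log2 of the share of peaks per 5 Mb window) along the 25 chromosomes of danRer7 (x axis). Each point is 1 of 278 windows; 7 of the 8 windows of chromosome 4 beyond 25 Mb lie at 0.30 to 0.47, above the highest other window at 0.29.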

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

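No paired analysis was possible because each group is 1 pooled list, and the labels name that list for all 3 samples, so leaving out a replicate could not be done either. The alternatives listed beforehand for transcription start site windows, gene lists and motifs were not run, since no danRer7 annotation or genome was used here. The 3 alternatives on height were chosen after seeing the data. Under the 9 alternatives the ratios stayed above 1, the chromosome 4 contrast stayed above 0, and mCherry only held the highest share of double positive peaks. Some orders did change. The double positive list held more of the mCherry only peaks than the double negative list did in 3 of the 9, and the mCherry only list held more of the GFP only peaks than the double negative list did with lists of equal length and at height 5 or more in every list. The GFP only share of double positive peaks exceeded the double negative share in 3 of the 9. Peaks of double positive alone outnumbered those shared with mCherry only with lists of equal length (16481 against 11580) and with reciprocal overlap of 50% (14096 against 11332). Exclusive GFP only peaks outnumbered double negative ones at height 10 or more in the counted list (2765 against 1848). With lists of equal length, peaks of double positive alone outnumbered those of mCherry only alone (16481 against 9884). A stricter threshold on the counted list alone shortens each class by construction. Equal length keeps the double positive list whole and shortens the others, so the class of double positive alone can only grow. Reciprocal overlap of 50% is a stricter rule of sharing, so each class of 1 list alone can only grow. The cause of the other changes was not tested. Counts and ratios of counts were held unmoved within 1.5 times the reported value. Shares, Jaccard indices and the chromosome 4 contrast were held unmoved within their 95% counting intervals, and closeness within the range its draws give. For Jaccard indices each base was counted as a separate trial. Their intervals are thus very narrow, and a slight shift counts as moved. By these tolerances, 25 of 45 alternative values of secondary results moved and 20 did not, and none moved without the mitochondrial genome. There were 240 alternative values in all. Most of those of the main results moved too, and the next paragraph lists the values that did. The number of runs was 14 at height 7 or more and 3 at height 10 or more in the counted list. Depth limits low peaks, since the fewest reads in a called peak were 10 in double positive and 11 in the other lists, and absence of a peak is not absence of accessibility.

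At −log10 q of 5 or more in every list, the peak counts were 4562 for double positive alone and 884 for double positive and GFP only. The ratio of both shared classes was then 9.15. At −log10 q of 5 or more in every list, of double positive peaks 88.9% lay in mCherry only, 72.2% in GFP only and 73.8% in double negative, and of mCherry only peaks 59.0% lay in double positive, 65.4% in GFP only and 70.6% in double negative. At −log10 q of 5 or more in every list, of GFP only peaks 49.0% lay in double positive and 66.9% in mCherry only, and of double negative peaks 57.1% lay in mCherry only and 54.4% in GFP only. At −log10 q of 5 or more in every list, the Jaccard index was 0.518 for double positive with mCherry only, 0.393 for double positive with GFP only, 0.322 for double positive with double negative, 0.460 for mCherry only with GFP only, 0.430 for mCherry only with double negative and 0.393 for GFP only with double negative. When the counted list alone had to reach −log10 q of 5, the peak counts were 2549 for double positive alone, 599 for double positive and GFP only, 7897 for mCherry only alone, 15177 for GFP only alone and 28744 for double negative alone. The ratio of both shared classes was then 11.2. When the counted list alone had to reach −log10 q of 5, of double positive peaks 93.3% lay in mCherry only, 78.7% in GFP only and 79.8% in double negative, and of mCherry only peaks 68.5% lay in double positive, 73.9% in GFP only and 77.9% in double negative. When the counted list alone had to reach −log10 q of 5, of GFP only peaks 57.4% lay in double positive, 74.7% in mCherry only and 76.4% in double negative, and of double negative peaks 47.6% lay in double positive, 67.3% in mCherry only and 64.4% in GFP only. Given lists of equal length, the peak counts were 16481 for double positive alone, 3271 for double positive and GFP only, 9884 for mCherry only alone and 24560 for double negative alone. Given lists of equal length, of double positive peaks 73.8% lay in mCherry only, 60.4% in GFP only and 56.8% in double negative, and of mCherry only peaks 72.4% lay in double positive and 63.4% in double negative. Given lists of equal length, of GFP only peaks 59.8% lay in double positive, 66.5% in mCherry only and 60.8% in double negative, and of double negative peaks 55.3% lay in double positive, 63.0% in mCherry only and 59.9% in GFP only. Given lists of equal length, the Jaccard index was 0.537 for double positive with mCherry only, 0.404 for double positive with GFP only, 0.354 for double positive with double negative, 0.461 for mCherry only with GFP only, 0.434 for mCherry only with double negative and 0.395 for GFP only with double negative. By reciprocal overlap of 50%, the peak counts were 14096 for double positive alone, 3905 for double positive and GFP only and 27090 for mCherry only alone. By reciprocal overlap of 50%, of double positive peaks 73.8% lay in mCherry only, 61.1% in GFP only and 59.8% in double negative, and of mCherry only peaks 49.8% lay in double positive, 56.8% in GFP only and 60.9% in double negative. By reciprocal overlap of 50%, of GFP only peaks 40.1% lay in double positive, 55.1% in mCherry only and 56.0% in double negative, and of double negative peaks 32.6% lay in double positive, 49.1% in mCherry only and 46.6% in GFP only. From summits within 250 bp, of double positive peaks 80.0% lay in mCherry only, 67.6% in GFP only and 68.1% in double negative, and of mCherry only peaks 54.0% lay in double positive, 61.9% in GFP only and 67.1% in double negative. From summits within 250 bp, of GFP only peaks 44.3% lay in double positive, 60.0% in mCherry only and 63.1% in double negative, and of double negative peaks 37.2% lay in double positive, 54.1% in mCherry only and 52.5% in GFP only. With height 5 or more in every list, the peak counts were 1009 for double positive and GFP only, 10360 for mCherry only alone and 18537 for GFP only alone. The ratio of both shared classes was then 8.39. With height 5 or more in every list, of double positive peaks 87.1% lay in mCherry only, 69.5% in GFP only and 70.6% in double negative, and of mCherry only peaks 63.9% lay in double positive, 65.0% in GFP only and 68.9% in double negative. With height 5 or more in every list, of GFP only peaks 53.1% lay in double positive, 67.7% in mCherry only and 66.9% in double negative, and of double negative peaks 43.2% lay in double positive, 57.4% in mCherry only and 53.7% in GFP only. With height 5 or more in every list, the Jaccard index was 0.542 for double positive with mCherry only, 0.406 for double positive with GFP only, 0.336 for double positive with double negative, 0.463 for mCherry only with GFP only, 0.428 for mCherry only with double negative and 0.388 for GFP only with double negative. With height 7 or more in the counted list, the peak counts were 1045 for double positive alone, 4270 for double positive and mCherry only, 161 for double positive and GFP only, 1859 for mCherry only alone, 6303 for GFP only alone and 7359 for double negative alone. The ratio of both shared classes was then 26.5. With height 7 or more in the counted list, of double positive peaks 96.5% lay in mCherry only, 82.8% in GFP only and 83.2% in double negative, and of mCherry only peaks 86.1% lay in double positive, 84.5% in GFP only and 84.9% in double negative. With height 7 or more in the counted list, of GFP only peaks 70.7% lay in double positive, 82.5% in mCherry only and 83.6% in double negative, and of double negative peaks 64.5% lay in double positive, 83.1% in mCherry only and 78.8% in GFP only. With height 10 or more in the counted list, the peak counts were 325 for double positive alone, 2516 for double positive and mCherry only, 43 for double positive and GFP only, 408 for mCherry only alone, 2765 for GFP only alone and 1848 for double negative alone. The ratio of both shared classes was then 58.5. With height 10 or more in the counted list, of double positive peaks 98.4% lay in mCherry only, 86.5% in GFP only and 86.1% in double negative, and of mCherry only peaks 94.4% lay in double positive, 90.4% in GFP only and 89.9% in double negative. With height 10 or more in the counted list, of GFP only peaks 78.6% lay in double positive, 86.5% in mCherry only and 88.2% in double negative, and of double negative peaks 77.3% lay in double positive, 92.2% in mCherry only and 88.1% in GFP only.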

Other observations

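The tests in this part were chosen after the results they bear on had been seen, and so were closeness and the chromosome 4 contrast, to which the alternatives fixed beforehand were applied later. The ratio of classes with lists of equal length was fixed before the data were examined, and its bound was set afterwards.

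Peaks of 1 list alone differed between the lists in their closeness to regions shared by both mCherry-positive lists. Of the peaks of the double positive list alone, 15.5% lay within 10 kb of a region shared by both mCherry-positive lists, against a mean of 11.0% and a maximum of 11.9% in matched draws. Of the peaks of the mCherry only list alone, 15.3% did, against 10.2% (maximum 10.9%). Of the GFP only peaks alone, 11.7% did, against 12.3% (minimum 12.0%), and of the double negative peaks alone 8.14% did, against 12.9% (minimum 12.5%). For a class of 1 list alone the draws hold only peaks also called in another list. Values below the draws can therefore not be read as avoidance of the shared regions. Peaks of the double positive list alone also lay within 10 kb of GFP only peaks alone more often than in any draw (37.9%, maximum 34.9%). The same held for mCherry only peaks alone (24.9%, maximum 23.5%) and, barely, for regions shared by both GFP-positive lists (3.35%, maximum 3.32%). It did not hold for double negative peaks alone (45.3%, draws 44.5% to 47.0%). For the first closeness the ratio to draws in the double positive list was 1.42, and lay between 1.24 and 2.77 under the 9 alternatives.

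Of the double positive peaks with 1 partner list, 8847 had mCherry only as that partner, 2257 double negative and 2154 GFP only. With lists of equal length the ratio of the mCherry only class to the GFP only class was 3.54. As called, the GFP only list was the longer of these partners, with 138366 peaks against 134262. The number of peaks could therefore not favour mCherry only. Its list did cover more bases (57.6 against 55.1 Mb) and had the higher background (4.46 against 4.26 reads). Placed at random, double positive peaks met mCherry only slightly more often than GFP only (8.22% against 8.18%). Equal length fixes the number of peaks alone, so the ratio at that setting cannot decide on covered bases or depth. Double positive cells carried into the mCherry only gate may give the same pattern. In 4.61% of the 8847 shared regions, or 408, the mCherry only height lay above the double positive height with exact Poisson intervals apart, close to the bound of 5% that was set. The double positive height lay above in 1151 regions (13.0%), as carried cells would give, and the intervals overlapped in 82.4%. These intervals leave out variation between separately sorted samples, so carried cells and a shared state of mCherry-positive cells cannot be told apart. That shared state was not tested otherwise.

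Regions open in all 3 reporter-positive fractions and not in the double negative list may reflect mCherry-positive cells carried into the GFP only gate. If 1 constant share of such cells were the whole cause, GFP only height above background would follow that of the mCherry-positive lists in every region. Of 1914 regions with height 10 or more in both mCherry-positive lists and no double negative peak, 1055 had no GFP only peak, a kind of count first taken as the test, on taller regions, and set aside because a small constant share can give it too. With the best single share, 19%, 22.1% of the regions (Wilson 20.3 to 24.0) lay outside their Poisson limits, 382 of them above. These limits leave out variation between separately sorted samples, so carried cells and a shared state of the 3 fractions cannot be told apart.

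The larger share of peaks on chromosome 4 in the GFP-positive lists was not confined to low peaks. The contrast was 0.45 among peaks of height 7 or more and 0.26 (0.11 to 0.41) at height 10 or more, where it was lower than over all peaks. At height 10 or more, however, the counts beyond 25 Mb were close: 327 double positive, 340 mCherry only, 363 GFP only and 334 double negative. The contrast at that height rests mostly on list length, with 30243, 36647, 32115 and 36394 peaks in the same order. At height 7 or more the counts were 635, 625, 849 and 689. At height 5 or more in every list, with height counted over the background of each list, the contrast was 0.48 (0.40 to 0.55). This argues against a calling limit that varies with depth as the whole cause. The same height stands for fewer reads in the shallower double positive list. Counting noise is thus not held alike, and depth stays open in that respect. With lists of equal length the contrast was 0.79, but that setting keeps the double positive list whole and removes the weakest peaks of the others. Peaks beyond 25 Mb were low, with a median height of 4.93 in double negative against 5.82 over that list. In mCherry only these were 4.93 and 6.28. Trimming can thus raise the contrast by itself, and the 0.79 cannot decide on depth or low peaks. A first test on depth, the GFP only share minus that of the shallower double positive list (0.156 percentage points), was set aside because it compares single lists by counting error only. Variation between sorted samples was not measured and stays open. A state tied to sele:GFP is a candidate explanation that stays open as a hypothesis. Mapping of reads in repeated sequence was not tested, as no mapping qualities were used here.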
